A study of Homo sapiens with 6 samples.

How the data were processed

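Total RNA of 3 FHC and 3 HCT116 samples was extracted with Trizol, amplified with random primers and labelled with Cy3, per the labels' protocols. Each sample was hybridised to 1 array of 62921 spots. The deposited scanner tables hold fluorescence intensity per spot, made with Agilent Feature Extraction 11.0.1.1 per the file headers. In the processed intensity of those deposited files the background had been subtracted, and low signals were replaced by small positive values. No normalization between arrays had been done in these columns. The median pixel intensity of each spot and of its local background was also used from the deposited files. The series value table deposited by the authors holds log2 values of 60495 probes with nearly equal quartiles on the 6 arrays. Its column medians were 5.92 (FHC 1), 5.91 (FHC 2), 5.92 (FHC 3), 5.91 (HCT116 1), 5.92 (HCT116 2) and 5.92 (HCT116 3). Each column correlated best with its own array's scanner values, at r of at least 0.9987. The normalization behind that table is not stated, and it was used as an alternative only. It lacks the 50 probes that carry an accession.

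The log2 of the processed signal minus each array's 75th percentile over spots not marked as controls was analysed. Spots flagged as outliers were left out, and spots of a probe were averaged. Saturated spots did not occur. Probes of 3 kinds that the scanner files do not mark as controls were left out of the tests, because their names mark them apart from the other probes and the authors' value table lacks them. These were 60 named Negative, 20 named CUST and 102 named ASSPINKEIN. Probes were tested where most of their spots were flagged well above background on at least 3 of the 6 arrays, which left 51861 of 60546. The groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested probes and no covariate. A probe was called at an adjusted p under 0.05 and at least a 2-fold difference, and differences are HCT116 minus FHC. Where no array of a line had the probe well above background, a lower bound is given in place of the fold, and levels below the 95th percentile of the Negative probes are also set at that percentile, a choice made after the data were seen. Groups were taken from the sample titles.

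Gene names were taken from transcript accessions, which the files give for 50 probes of 10 spots each. A RefSeq gene table of assembly GRCh38.p14 matched 49 of them, and 1 stayed unmatched. The array's grid was built on another assembly, so no coordinates are given. The rule for named genes, fixed before the data were examined, took up to 12 genes in each direction with the largest log2 difference among named probes. They had to pass the threshold and be well above background on all 3 arrays of the brighter line. It added up to 3 measured members of each fixed gene list. Genes of the X-inactivation centre and of chromosome Y were excluded. In addition, 1 gene that the rule names is counted but not described here. The planned counts over lncRNA and mRNA probes, the gene list tests and the correlation of lncRNAs with partner genes were not run, since the files used here pair no RNA type or name with the other probes. Counts by parts of the probe identifier are given in their place and were chosen after the data were seen.

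The test was checked on simulated values for the comparison of HCT116 with FHC over 51861 probes, with the probes' own means and spreads. At each fold 50 probes were changed. It called 0% of probes changed 1.5-fold, 40% of those changed 2-fold, 90% of those changed 4-fold and 100% of those changed 8-fold, with 2 false calls. Of the probes changed 2-fold 60% passed the adjusted p, and the 2-fold minimum lowered the share called. In the data far more probes, 9198, passed the adjusted p. The adjustment was therefore stricter in the simulation, and its rates and false calls do not carry over to the data. The number of arrays limits the precision. For the 48 tested probes with 10 spots each, the median SD between spots of an array was 0.049 and that between arrays of a line 0.110, on the log2 scale.

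Alternatives were quantile normalization, another background correction, other centring, other filters on dim probes, a floor, an intensity trend in the variance, a test without shared variances, the authors' table, replicate number or slide as a block, other fold thresholds and leaving out each array. The mean spot signal is not among the columns used here, so normexp was run on the median signal, with an offset of 50 intensity units added. Exact permutation tests were used for values per array. The scanner headers give 2 slides, and scan settings were not compared. Figures were drawn with matplotlib 3.10.9.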

Results

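RNA from HCT116 cells, a human colorectal carcinoma line, was compared with RNA from FHC cells, a line of normal human colon epithelium. Each line was measured on 3 arrays, 1 array per sample, with 1 dye (Cy3). The arrays carried probes for long non-coding RNAs (lncRNAs) and for mRNAs, and the stated purpose was to find lncRNAs whose levels differ between the lines. The labels give the lines different culture media, McCoy's 5A for HCT116 and DMEM for FHC, so line and medium cannot be told apart. The labels do not say that the 3 samples of a line were separate cultures, so the p-values below measure the spread between these samples, which may be technical. The 75th percentile of the processed signal lay between 133 and 159 intensity units on the 6 arrays, and no spot was saturated. Pairs of arrays of the same line correlated at r = 0.988 to 0.992 over probes, and pairs across the lines at 0.942 to 0.947. Probes are not independent replicates.

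HCT116 cells had far higher signal than FHC cells for COL13A1, a transmembrane collagen, and higher signal for TCF7, a transcription factor of the WNT pathway, and SPP1, the secreted phosphoprotein osteopontin. FHC cells had higher signal for SAA4, a serum amyloid A apolipoprotein, and NMI, an interferon-inducible protein that binds MYC and STAT proteins. These genes belong to the 49 for which the array files give a transcript accession that could be matched to a symbol. The other probes carry only the maker's identifiers, and their genes are not named here.

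Of the 47 named genes bright enough to be tested, 14 passed limma's test at an adjusted p under 0.05 with at least a 2-fold difference. In HCT116, 11 of them were higher and 3 were lower. COL13A1 was not well above background on any FHC array. Its mean log2 signal relative to the 75th percentile of the array was 3.19 ± 0.18 (SD, n = 3) in HCT116, with a limma adjusted p of 1.52e-08. It lay at least 19.9-fold above FHC when each FHC array was set at the 95th percentile of its probes named Negative. The bound was at least 68.4-fold when each FHC array was set at its lowest signal among probes well above background, a level below many Negative probes. TCF7 had a fitted log2 difference of 2.57 ± 0.13 (SE) and a limma adjusted p of 2.14e-06. SPP1 had a fitted difference of 1.67 ± 0.11, and CPS1, the mitochondrial enzyme at the entry of the urea cycle, one of 1.47 ± 0.12. In FHC these 3 genes did not exceed the 95th percentile of the Negative probes on any array, so their fitted differences are not ratios of 2 specific signals. Against that percentile, HCT116 was 2.32-fold higher for TCF7, 1.71-fold for SPP1 and 1.39-fold for CPS1. On HCT116 arrays 1 and 2, CPS1 (-0.60 and -0.83) was dimmer than the probe Negative008 (-0.46 and -0.61). Specific CPS1 signal in HCT116 is therefore not shown. PLA2G4A, the cytosolic phospholipase that releases arachidonic acid, was 2.23-fold higher (1.16 ± 0.15). The limma adjusted p of SPP1, CPS1 and PLA2G4A was at most 0.000587.

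The other 6 named genes higher in HCT116 lay between 2.05-fold and 2.79-fold. ATAD2, a bromodomain ATPase of chromatin, was 2.79-fold higher in HCT116 (log2 difference 1.48 ± 0.11, SE). SMARCAD1, a chromatin remodeller, was 2.43-fold higher (1.28 ± 0.13). DSCC1, which loads the replication clamp and acts in sister chromatid cohesion, was 2.23-fold higher (1.16 ± 0.11). WRN, a RecQ helicase, was 2.17-fold higher (1.12 ± 0.12). CHAF1B, a subunit of the chromatin assembly factor that places histones on new DNA, was 2.16-fold higher (1.11 ± 0.12). ZZZ3, a subunit of a histone acetyltransferase complex, was 2.05-fold higher (1.04 ± 0.12). The limma adjusted p of these 6 genes was at most 0.000296, and on all 3 HCT116 arrays each of them lay above all 3 FHC arrays. The lines were separated in this way for 3253 of the 3259 probes called on the whole array, so this adds no support beyond the call.

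In the other direction, SAA4 had a fitted log2 difference of -3.10 ± 0.11 (SE) and a limma adjusted p of 3.33e-07. No HCT116 array had SAA4 above the 95th percentile of its Negative probes, and FHC lay 4.20-fold above that level. NMI was 3.48-fold lower (-1.80 ± 0.10, adjusted p = 4.87e-06 by limma). NMI exceeded the Negative probes' percentile on all 6 arrays. The third gene of this direction is not described here.

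**Figure D1:**
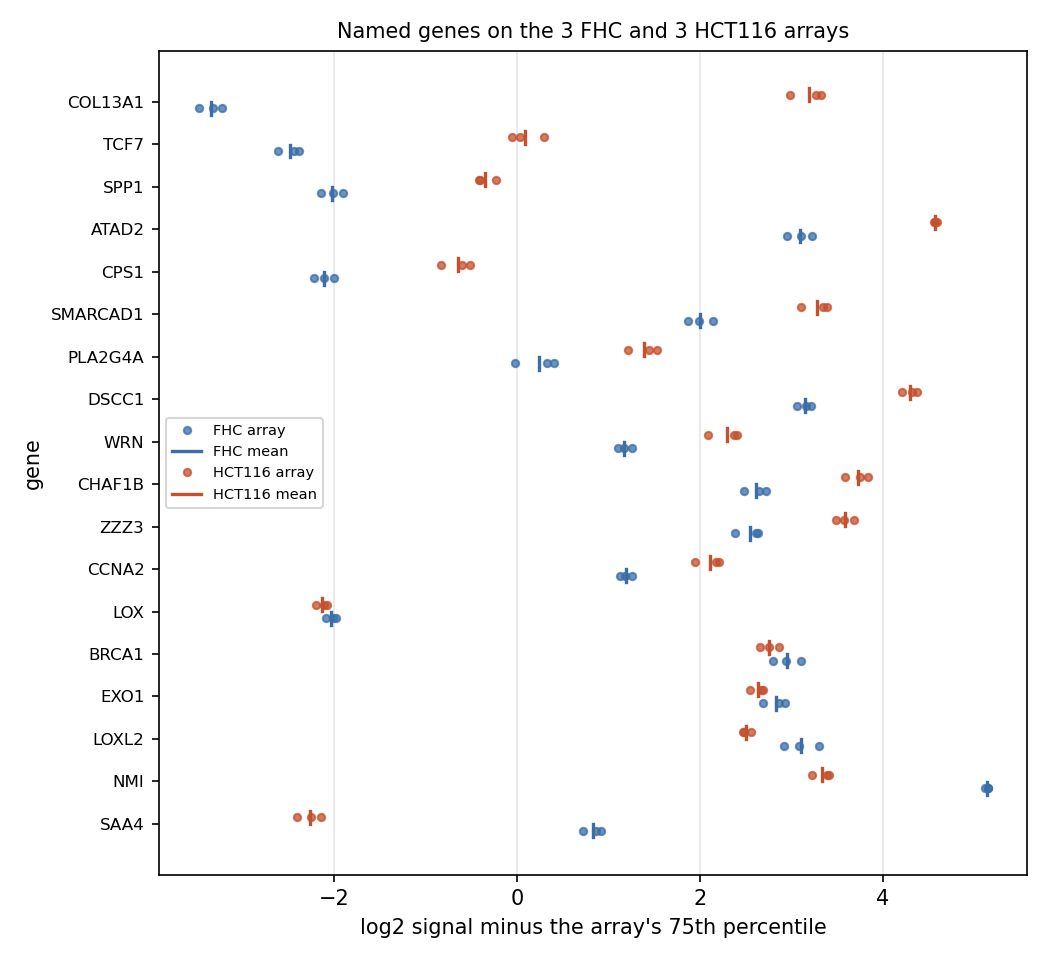
Log2 signal minus the array's 75th percentile (horizontal axis) for the genes named by rule, except 1 gene not described here (vertical axis), sorted by the difference between the lines. Points are the 3 FHC and 3 HCT116 arrays, and vertical strokes are the means of each line. COL13A1 lies at 3.19 in HCT116, where FHC was not well above background, and SAA4 at 0.84 in FHC and -2.27 in HCT116.

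Among the named genes, 19 more passed limma's adjusted p with less than a 2-fold difference, 15 higher in HCT116 and 4 higher in FHC. With slide as a block 8 of these 19 no longer passed, among them 3 of the 4 higher in FHC. All 8 kept their sign, with log2 differences of 0.36 to 0.63 in size against 0.35 to 0.60 before, while their SE was 0.15 to 0.21 with the block against 0.10 to 0.14 before. The following examples from them were chosen after their values were seen. UCHL5, a proteasome-bound deubiquitinase, differed by 0.98 ± 0.10 (log2, SE) and EIF5B, a translation initiation factor, by 0.93 ± 0.11. NOC3L, a nucleolar protein, differed by 0.89 ± 0.11 and RAD54B, a recombination factor, by 0.83 ± 0.10. POGLUT2, a protein glucosyltransferase of the endoplasmic reticulum, was lower in HCT116 at -0.82 ± 0.11. The remaining 14 tested genes did not pass, with log2 differences of at most 0.43 in size. CFTR, the epithelial chloride channel, and CD69, a lymphocyte activation marker, were not tested, because no array of either line had them well above background.

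Of the 28 gene lists fixed before the data were examined, 5 had any named probe, with at most 2 members each, so no list could be tested as a group. The WNT target list had TCF7 as its single measured member, which was higher in HCT116. With 1 member, adjusting over the list alone adds no further test. The proliferation list had CCNA2, the cyclin of S phase and mitotic entry, which was higher in HCT116 by 0.92 ± 0.11 on the log2 scale (limma adjusted p = 0.00052), short of 2-fold. The list of TGF-beta response and matrix remodelling had LOXL2, a lysyl oxidase that cross-links collagen, with a log2 difference of -0.60 ± 0.12 and a limma adjusted p of 0.00915. With slide as a block the LOXL2 difference was -0.63 and its limma adjusted p 0.0822, and within slide 1 the adjusted p was 0.131, the highest of a range over alternatives that began at 0.00106. The mesenchymal list had LOX, at -0.10 ± 0.10 (limma adjusted p = 0.591), but LOX exceeded the 95th percentile of the Negative probes on 0 of 6 arrays, so this value does not measure it. The mismatch repair and recombination list had EXO1, at -0.19 ± 0.11 (adjusted p = 0.325), and BRCA1, at -0.19 ± 0.12 (adjusted p = 0.358), both by limma. With quantile normalization BRCA1 stood at -0.36 with a limma adjusted p of 0.036, short of 2-fold, and over all alternatives the adjusted p ranged from 0.036 to 0.567.

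Across the whole array, 51861 of 60546 probes were tested, and 3259 (6.28%) differed at a limma adjusted p under 0.05 and at least 2-fold. Of these, 1697 were higher in HCT116 and 1562 were higher in FHC. This balance depended on the scaling, with 1580 against 1585 under quantile normalization, 1578 against 1578 in the authors' table and 1831 against 1477 when arrays were centred on the median of tested probes. At least 4-fold differences were seen for 1027 probes, 498 higher in HCT116 and 529 higher in FHC, and at least 16-fold fitted differences for 252. HCT116 alone gave signal well above background for 268 of the called probes, and FHC alone for 229, so the fitted folds of those probes are not measured on both sides. The 3 arrays of one line did not overlap the 3 of the other for 32.5% of tested probes, where chance gives 10%. The median difference over all tested probes was -0.03 on the log2 scale, and the median SD within a line was 0.14.

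Probes whose identifiers contain LNC, ASHG19AP1B (here AP1B) or ASHGV make up nearly the whole array, and the files do not define these parts of the names. Among 22866 tested probes with LNC, 1230 (5.38%) differed, 575 higher in HCT116 and 655 higher in FHC, and 613 against 623 when arrays were centred on the median of tested probes. When adjusted over those probes alone the count was 1228. Among 19293 tested AP1B probes 1616 (8.38%) differed, 926 higher in HCT116 and 690 higher in FHC, and 822 against 723 under quantile normalization. Among 9654 tested ASHGV probes 399 (4.13%) differed, 185 higher in HCT116 and 214 higher in FHC, and 203 against 197 with the same median centring. With normexp on the median signal the calls fell to 475 for LNC, 992 for AP1B and 138 for ASHGV probes. The calls thus lay more often on the HCT116 side for AP1B probes (57.3%) than for LNC probes (46.7%), a difference of 10.6 percentage points with a 95% interval of 6.87 to 14.2 that treats probes as independent. At 4-fold the gap was smaller, 51.1% for AP1B against 45.8% for LNC probes.

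**Figure D2:**
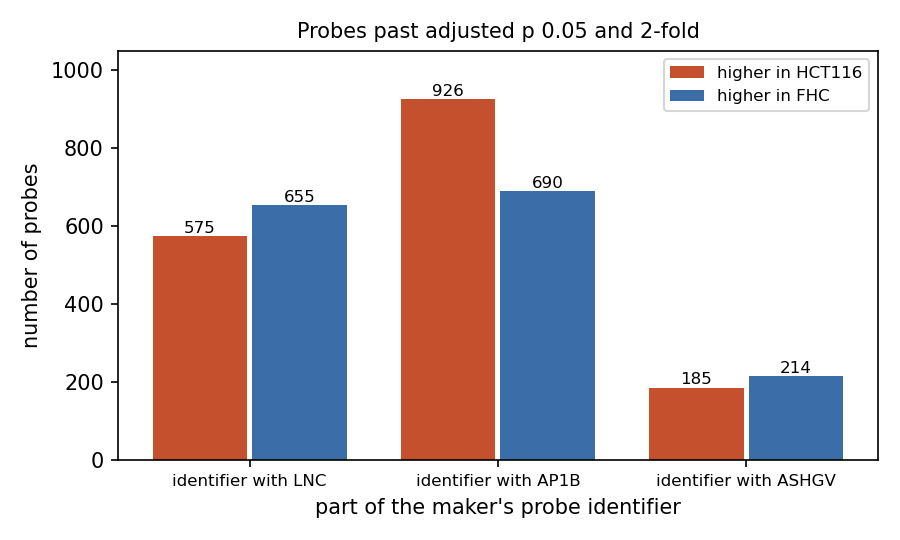
Number of probes (vertical axis) past a limma adjusted p of 0.05 and 2-fold, for 3 kinds of probe identifier (horizontal axis), with bars for probes higher in HCT116 and higher in FHC. AP1B probes had 926 calls higher in HCT116 against 690 higher in FHC, and LNC probes 575 against 655.

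The following 4 unnamed probes, chosen after their values were seen, are 1 AP1B and 1 LNC probe in each direction. They were picked by fitted difference, whose size depends on the floor of the dimmer line, so no rank is given. With the dimmer line set at the 95th percentile of the Negative probes, ASHG19AP1B100068051V5 was at least 208-fold and ASHG19LNC1A100097067V5 at least 7.41-fold higher in HCT116, and FHC was not well above background on any array. On the same terms ASHG19AP1B100192088V5 was at least 68.2-fold and ASHG19LNC1A103955190V5 at least 14.4-fold higher in FHC, and HCT116 was not well above background on any array. The limma adjusted p of each was at most 2.28e-08.

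The share of probes well above background was 84.2% ± 1.28 (SD, n = 3) in FHC and 83.9% ± 2.99 in HCT116. The exact two-sided permutation p was 0.9, and 3 against 3 arrays cannot go below 0.1, so this test could not show a difference. The flag was lenient, since probes named Negative passed it at 72.2% in FHC and 66.7% in HCT116. Above the 95th percentile of those Negative probes lay 47.9% ± 3.61 of probes in FHC and 49.6% ± 2.69 in HCT116. TCF7, SPP1, CPS1, COL13A1 and SAA4 exceeded that level on the 3 arrays of the brighter line alone, and the other called named genes on all 6.

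The 3 FHC arrays and 1 HCT116 array shared slide 1, and the other HCT116 arrays lay on slide 2. With slide as a block 3278 probes were called, of which 2909 were among the 3259, and within slide 1 3243 were called, of which 2878 were among them. Both fits rest on the same contrast of 1 HCT116 array with 3 FHC arrays, since slide 2 holds no FHC array, and within slide 1 the spread comes from FHC alone. All 14 named genes stayed called. Background correction with normexp on the median signal, chosen after the data were seen, reduced the calls to 1614 and brought COL13A1 to a log2 difference of 4.20, TCF7 to 1.34 and SAA4 to -1.80. It also took SPP1 (0.86), CPS1 (0.71), PLA2G4A (0.92), WRN (0.96) and ZZZ3 (0.96) below 2-fold, and quantile normalization did so for DSCC1 (0.96), WRN (just under 1.00), CHAF1B (0.95) and ZZZ3 (0.87). Normexp here added an offset of 50 intensity units to every spot, where the arrays' median processed signal was 54 to 72. Such an offset by itself makes the log2 differences of dim probes smaller. ZZZ3 also fell short of 2-fold without FHC replicate 2 (0.96) and without HCT116 replicate 1 (0.99).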

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

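The tests of non-specific signal, of slide and of normalization in this section were chosen after the results were seen. Probes outside the comparison gave signals of their own, and their adjusted p-values are over these 250 probes alone. Probes named Negative were flagged well above background at 72.2% in FHC and 66.7% in HCT116. Control probes for human housekeeping genes were higher in HCT116, GAPDH by 0.58 (3' probe, limma adjusted p = 0.0464) and 0.51 (5' probe, limma adjusted p = 0.0483) and PGK1 by 0.67 at the 3' probe (limma adjusted p = 0.0179), on the log2 scale. The direction held for these probes with quantile normalization, median centring and normexp. The 5' probe of PGK1 differed by 0.15 (limma adjusted p = 0.79). The gap between 3' and 5' probes was larger in HCT116 by 0.07 for GAPDH and 0.52 for PGK1, and the exact two-sided permutation p was 0.2 for both, where 0.1 is the smallest possible. Probe CUST_3_PI418767722 was higher in HCT116 by 2.33 (log2) and CUST_14_PI418767722 by 1.12, while CUST_18_PI418767722 stood at -1.19. The files do not say what these probes detect. Probe ASSPINKEIN100004308 stood at -1.13 and Negative039 at -1.16.

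The high share of Negative probes past the detection flag raises the question whether called probes rest on non-specific signal. Probes with no stated human target (Negative, ERCC, E1A, ETG and DCP) that passed the detection filter numbered 93. They were compared with the other tested probes below and above the 95th percentile of their own mean signal. Tested probes dimmer than the dimmest of these 93 were left out of both parts. Below the percentile 1 of 88 such probes was called (exact 95% upper limit 6.17%), against 4.31% of 28228 tested probes in that range (Fisher's exact p = 0.188). Above it lay 5 such probes, too few to compare with the 8.18% called among 23299 tested probes. The brighter line lay above every Negative probe on all its arrays for 66.2% of calls (95% interval 64.5 to 67.8). Among all tested probes this held for 35.6%. The calls were thus not confined to the signal range of the Negative probes. This cannot rule out non-specific signal, since calls select probes with a bright line and brightness alone does not show specific binding. The share above every Negative probe was 22.1% (269) of the 1217 dim calls and 99.0% (1887) of the 1906 brighter ones. The signal ranges largely set this split. Over all 3259 calls 2156 met it, and the calls dimmer than the dimmest of the 93 probes are in neither part. In addition, 2663 probes were called when tested probes had to exceed the Negative probes' 95th percentile on 3 arrays. Non-specific signal could account for some calls among dim and brighter probes, where the non-target probes are too few to tell. No biological explanation was tested.

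Calls of AP1B probes lay on the HCT116 side more often than calls of LNC probes, by 10.6 percentage points at 2-fold and by less at 4-fold (51.1% against 45.8%). Signal level was tested with a Mantel-Haenszel common odds ratio over 10 bins of mean signal, which was 1.33 (95% interval 1.14 to 1.55) against 1.53 without that adjustment, so level may account for part of the lean and not the whole. With quantile normalization the difference was 7.08 points (3.33 to 10.8), which argues against scaling between arrays as the whole cause. Within slide 1 it was 12.7 points, but that slide holds 1 HCT116 array, so slide stays open. The intervals treat probes as independent, and the readings on level and scaling hold only if that is so. Probes that vary together would make the intervals too narrow. A difference between the cell lines, or between their media, stays open and was not tested.

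Over 10 splits of the 6 arrays into 3 and 3, the real split alone (1 of 10) gave as many calls, for all probes and for each kind of identifier. It gave 3259 calls in all, 1230 with LNC, 1616 with AP1B, 399 with ASHGV and 14 with an accession, and the highest count of any other split was 0 in each case. 10 splits are too few for a share under 0.05. Every other split mixes the lines, so the difference between the lines enters the spread within groups. The 0 calls there do not measure how often false calls arise.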

How the results depend on the processing

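Normexp on the median signal, folds against the Negative probes, calls within slide 1, the filter on Negative probes, 1 spot per probe and all counts by identifier were chosen after the data were seen. Among the calls shared with the 3259, no direction changed in any of the 23 alternatives. Several alternatives use the same log2 values and shared calls passed in both fits, so a change was hardly possible. Normexp called 1614 probes in all, 475 with LNC, 992 with AP1B, 138 with ASHGV and 9 with an accession. Its offset of 50 intensity units by itself lowers the differences of dim probes, and how much of the loss this explains was not tested. Requiring signal well above background on all 6 arrays left 260 ASHGV calls, with fewer probes tested. Without a minimum fold the counts were 9198 in all, 3556 with LNC, 4492 with AP1B, 1116 with ASHGV and 34 with an accession. At 4-fold they were 1027, 325, 579, 119 and 4. All other counts stayed within 1.5 times. Over all probes these were 3165 with quantile normalization, 3156 with the authors' table and 2468 with the filter on all 6 arrays. Leaving out each array gave 3240 to 3370. Of the 14 named genes, 7 stayed called in every alternative that kept the 2-fold threshold and could be run on them (among them COL13A1, TCF7, ATAD2, SMARCAD1, SAA4 and NMI), except that the filter on all 6 arrays does not test COL13A1. The other 7 fell below 2-fold in at least 1 alternative, and ZZZ3 alone did so when an array was left out. CCNA2 reached 2-fold without HCT116 replicate 2 (1.00). UCHL5 reached it in 6 alternatives, up to 1.06. With the replicate number as a replicate block 3267 probes were called, 3252 of them shared. Same-numbered arrays did not deviate together (r = -0.16, -0.06 and -0.01). Samples handled as pairs can lack a shared deviation, so whether the numbers pair the samples stays open. The difference in the share of probes well above background was -0.30 percentage points, -0.03 with the software's other detection flag and -1.34 to 1.42 with 1 array left out. The authors' table cannot be used for the named genes, which it lacks. The tests of gene lists, of RNA classes and of partner genes, and their alternatives, were not run, nor was normexp on the mean signal. Signal over background limits the dim probes, since probes named Negative often passed the detection flag.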

Other observations

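The tests of the gene group and of normalization below were chosen after the values were seen, and the test of signal level before its result was known. Of the named genes, 26 passed limma's adjusted p with higher signal in HCT116 and 7 with lower signal. With slide as a block 8 of these 33 no longer passed, 3 of them among the 7, though all 8 kept their sign and a size of 0.36 to 0.63 against 0.35 to 0.60 before, with larger SE. Among 19 of the 47 that act in DNA replication, repair or cell division, grouped after their values were seen, 13 passed and were higher in HCT116 and 0 passed in the other direction. Of the other 28 named genes 20 passed, so the share that passed was no higher in this group. With slide as a block 4 of the 13 no longer passed, with differences of 0.42 to 0.53 against 0.35 to 0.44 before and SE of 0.15 to 0.16 against 0.10 to 0.11. The 13 include CENPQ (0.51 ± 0.11, log2 difference and SE), a kinetochore protein, and WDHD1 (0.44 ± 0.11), a replisome protein. Passing members of smaller difference did not all hold with quantile normalization. The limma adjusted p was then 0.0677 for CENPQ, 0.15 for WDHD1, 0.267 for PRIM1, 0.303 for SMC6 and 0.226 for SPDL1. BRCA1, of the same group, then passed in the other direction (-0.36, limma adjusted p = 0.036). For WDHD1 the limma adjusted p ranged from 0.00334 to 0.15 over all alternatives. For CENPQ the lowest was 0.00115, and it was 0.0685 with 1 spot per probe. DTL (0.11 ± 0.10), an adaptor of replication-coupled ubiquitination, and KIF20A (0.29 ± 0.16), a mitotic kinesin, did not pass.

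The named genes as a set lay on the HCT116 side, with a median log2 difference of 0.43. Signal level was tested against 10000 random sets of AP1B probes of the same mean signal, whose medians centred on 0.13 with 95% between -0.01 and 0.30. The named genes stood at percentile 99.97 of these. This argues against signal level as the whole cause only if the genes vary independently, as the random sets assume. Named genes that vary together would make the percentile too extreme. With quantile normalization the median of the named genes was 0.24, at percentile 99.67 of matched sets. The size of the shift thus depended on the scaling. By this test, with the same limit, scaling does not account for all of it. One hypothesis is that genes of DNA replication, repair and cell division in this panel may carry the shift. Their median was 0.44 against 0.29 for the other 28 named genes, a difference of 0.15 with a bootstrap 95% interval of -0.52 to 0.78 and a two-sided permutation p of 0.5. This leaves the hypothesis open, since the interval holds both 0 and the size of the shift, 0.30. Slide was not tested for this shift and stays open. A difference of the cell lines or their media stays open as well.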
